A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

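Poly(A) RNA of budding yeast, *Saccharomyces cerevisiae*, was measured by strand-specific sequencing in 24 libraries. Per the labels' protocols, cultures in the rich medium YPD were used at an A600 of 0.6 to 0.8, and auxin (indole-3-acetic acid, IAA) with beta-oestradiol was added for 60 min at 30 °C. The concentrations in the sample labels were 100 µM IAA and 1 µM beta-oestradiol. An inducible degron is a tag that lets an added compound trigger the destruction of the tagged protein, and the series names degron strains for DCP2 and for LSM1. RNA was extracted with hot phenol, selected on poly-T beads and made into libraries by the dUTP method, which marks the strand, per the labels' protocols. The labels gave 3 strains (wt, dcp2-ideg and lsm1-ideg), 2 times (before the addition, T0, and 60 min after it, T60) and 4 replicates for each of the 6 groups. Samples were assigned to groups by their titles alone.

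The deposited table holds whole-number counts of reads per feature, not normalized by the authors. Per the submitters' processing notes, STAR, featureCounts and the genome build sacCer3 were used, and their versions, the annotation and the strand setting were not given in the sources used here. The 12289 features included 5796 protein-coding genes, 1658 Xrn1-sensitive unstable transcripts (XUTs), 847 stable unannotated transcripts (SUTs), 925 cryptic unstable transcripts (CUTs), 1315 cryptic transcripts of another set named CUT_GIM in the table, 800 dubious open reading frames and 281 introns. Positions are those of the table, on sacCer3. As a check, the coding sequences of the R64 reference annotation were compared with the table, and 5404 of 5796 (93.2%) lay inside the feature of the same name. All columns of the table matched a sample.

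Overlaps between features were checked because the counting could split or repeat reads. In 1244 pairs of nested features on 1 strand, the inner feature never had more counts than the outer one, so that a read overlapping several features appeared to be counted in each. Only 767 XUTs and 180 SUTs overlapped no other feature on their strand, and 1409 protein-coding genes did overlap another, so classes were also summarised over features alone on their strand. Strand was checked with 67 XUTs that lie inside the opposite strand of 1 protein-coding gene of at least 100 CPM. Their median count per base was 3.88% of that of the gene (upper quartile 5.12%), and 64 of the 67 were under 10%. For 120 dubious open reading frames placed in the same way the median was 5.33% (upper quartile 10.4%), and 89 were under 10%. Counts of the opposite strand were thus mostly, not fully, kept apart. Protein-coding genes with a near-identical copy (at least 95% identity over at least 50% of the length, found with blastn 2.17.0) numbered 236, and their values are given as uncertain.

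Total counts per library ran from 41.8 M to 83.9 M (median 54.4 M, M standing for mega), and between 11633 and 12025 features had counts. The 10 most abundant features took 7.83% to 11.8% of a library. Protein-coding genes took 77.4% to 87.8% of the counts.

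Features with enough counts by edgeR's filterByExpr entered the tests, which kept 11776 and left out 513. Library sizes were scaled with TMM factors, which ran from 0.859 to 1.49 and were 1.29 to 1.49 in the dcp2-ideg T60 libraries. All 24 libraries were fitted in 1 edgeR quasi-likelihood model (edgeR 4.0.16, R 4.3.3) with a mean per group, 18 residual degrees of freedom and 6.72 prior degrees of freedom. The p-values are two-sided and adjusted by Benjamini and Hochberg over all features tested, a call is an adjusted p under 0.05, and every adjusted p of a gene is from this model. The standard error (SE) of a log2 change is its size divided by the square root of its F statistic. CPM are edgeR's library-scaled counts with TMM factors, given as mean ± SD over the 4 libraries of a group. There were 8 comparisons. The 3 main ones were the change from T0 to T60 in dcp2-ideg beyond that in wt, the same for lsm1-ideg, and the dcp2-ideg change against the lsm1-ideg change. The other 5 were T60 against T0 within each of the 3 strains and each degron strain against wt at T0.

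The 28 gene lists were ribosomal proteins, ribosome biogenesis, glycolysis, the nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, alternative carbon source use, the general stress response, heat shock factor targets, amino acid biosynthesis, sulfur amino acid and sulfate use, phosphate starvation, iron starvation, nitrogen catabolite repression, drug efflux, the galactose regulon, ergosterol synthesis, histones, G1 to S, G2 and M, M to G1, a-cell, alpha-cell and meiosis genes, decapping and 5'-3' decay factors, nonsense-mediated decay (NMD) factors, deadenylation and exosome factors, NMD-sensitive mRNAs of the literature and model mRNAs of decay studies. The mitochondrially encoded list had 0 measured members, so 27 were tested. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 27 lists, and again with an estimated correlation and with fry. Members were counted as called over all features and, in the words used below, adjusted over the list alone. Where only 1 count is given for a list, both counts were equal. Named genes were fixed by rule. For each main comparison they were the 10 largest rises and 6 largest falls among called protein-coding genes with a mean of at least 10 CPM whose T60 and T0 libraries of the responding strain did not overlap. For each other comparison they were the 5 largest in each direction, and for a list described up to 4 members with the smallest adjusted p. The lists, groups, tests, naming rule and first set of alternatives were chosen before the data were examined.

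Alternatives were median-of-ratios size factors, total count scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter at 10 CPM in 4 libraries, the replicate number as a block, the libraries of the compared groups alone, protein-coding features alone, T60 libraries alone, a 2-fold threshold, and leaving out each library and each replicate number. Others were chosen after seeing the data, namely features alone on their strand, a robust dispersion estimate, leaving out both libraries that stand apart (dcp2-ideg T0 replicate 4 and wt T60 replicate 3) and leaving out the dcp2-ideg pair of number 4.

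Whether replicate numbers pair samples was checked by correlating deviations from group means across features. Only T0 and T60 of dcp2-ideg had every pair over 0.1 (0.295, 0.152, 0.162 and 0.632), so the numbers were taken to pair samples there, from the data alone. The group means included number 4, which stood apart at T0, and this can raise the correlations of the other numbers. Pairing of those other numbers is thus not settled by the rule. In no other pair of groups did every pair exceed 0.1. No replicates were copies of each other, as the chi-square per feature between replicates was 17.9 to 594.

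The model was tested on simulated data for 4 comparisons, each with 100 features changed 1.5-fold and 100 changed 2-fold. For the dcp2-ideg response beyond wt, 6 and 32 of 100 were recovered (14.0% and 58.7% at 10 CPM or more) among 11729 features, with 2 false calls. For the lsm1-ideg response beyond wt, 7 and 23 of 100 were recovered (11.6% and 50% at 10 CPM or more) among 11727 features, with 1 false call. Within dcp2-ideg 27 and 64 of 100 were recovered among 11729 features, and within lsm1-ideg 29 and 54 of 100 among 11727. The chance level of overlap between responses sharing the wt libraries was simulated 20 times with no effect in any group.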

Results

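RNA was sequenced from 3 yeast strains before and 60 min after the addition of IAA and beta-oestradiol, with 4 libraries in each of the 6 groups. The wt strain carried no degron, the dcp2-ideg strain an inducible degron for DCP2, the catalytic subunit of the mRNA decapping enzyme, and the lsm1-ideg strain an inducible degron for LSM1, a subunit of the cytoplasmic Lsm1-7 ring that binds mRNA 3' ends and activates decapping. The title of the series asks how much Lsm1-7 contributes to the decay of unstable mRNAs. Total counts ran from 41.8 M to 83.9 M per library, and the wt T0 libraries averaged 57.7 ± 8.81 M (SD, n = 4). The first 3 principal components held 37.4%, 8.80% and 7.04% of the variance. The labels do not say that the replicates were separate cultures, so the p-values below measure only the spread between these samples, which may be technical.

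The mRNAs of both tagged genes were measured in every library. DCP2 (chromosome XIV, 402541 to 405613, minus strand) had 149, 133, 133 and 160 CPM in the wt T0 libraries of replicates 1 to 4, and 131, 135, 167 and 147 CPM in wt at T60. In dcp2-ideg it had 145, 123, 146 and 83.3 CPM at T0 and 67.8, 77.4, 77.6 and 49.5 CPM at T60. In lsm1-ideg it had 149, 141, 141 and 149 CPM at T0 and 133, 131, 129 and 132 CPM at T60. DCP2 thus fell in dcp2-ideg from 124 ± 29.3 to 68.1 ± 13.2 CPM (SD, n = 4), a log2 change of -0.87 ± 0.14 (SE, adjusted p = 1.8e-05, edgeR quasi-likelihood test). The change beyond wt was -0.88 ± 0.20 (adjusted p = 0.00136), and its adjusted p was 0.0941 under total count scaling. LSM1 (chromosome X, 186854 to 187813, minus strand) had 153, 162, 152 and 147 CPM in wt at T0 and 173, 161, 152 and 159 CPM at T60. In dcp2-ideg it had 164, 158, 159 and 170 CPM at T0 and 141, 124, 117 and 138 CPM at T60. In lsm1-ideg it had 101, 103, 103 and 99.0 CPM at T0 and 89.2, 85.3, 84.2 and 92.4 CPM at T60. LSM1 was lower in lsm1-ideg than in wt before any addition, with a log2 difference of -0.60 ± 0.080 (adjusted p = 0.000113). Its change from T0 to T60 within lsm1-ideg was -0.21 ± 0.080 (adjusted p = 0.213). Within dcp2-ideg, LSM1 changed by -0.32 ± 0.079 (adjusted p = 0.00145), a direction that turned to 0.22 under total count scaling. That LSM1 call was also lost at 10 CPM (adjusted p = 0.0932) and among protein-coding features alone (0.226). These values are of mRNA, and the proteins were not analysed here.

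**Figure D1:**
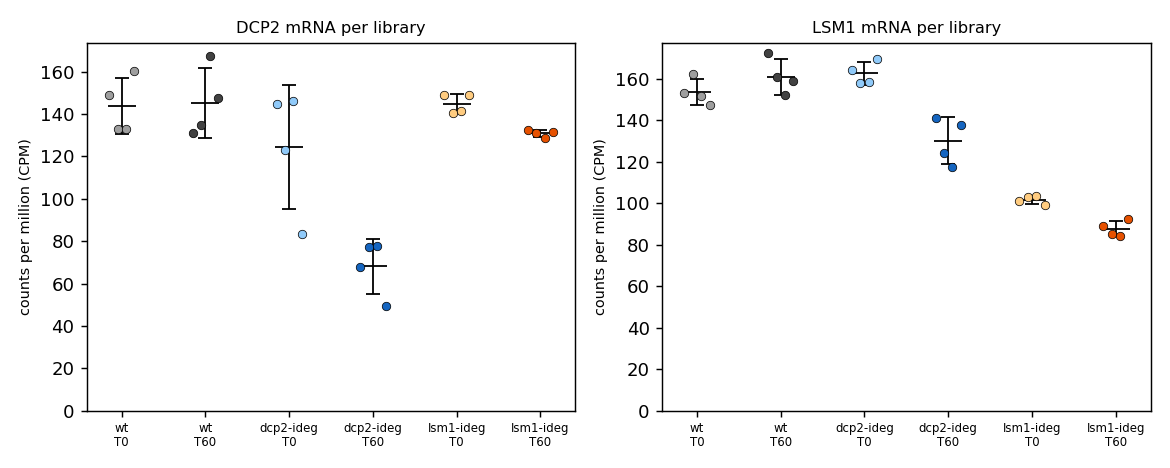
CPM of DCP2 and LSM1 (vertical axes) in each of the 24 libraries by strain and time, with points for libraries and bars for the mean ± SD of 4. DCP2 was lowest in the dcp2-ideg T60 libraries, at 49.5 to 77.6 CPM, and LSM1 in the lsm1-ideg T60 libraries, at 84.2 to 92.4 CPM.

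The first comparison asked which RNAs changed after 60 min in dcp2-ideg beyond the change in wt. The stress-regulated gene RTC3 (chromosome VIII, 280743 to 281327, plus strand) rose most among the named genes. It went from 6.71 ± 0.922 to 178 ± 38.4 CPM in dcp2-ideg and from 6.01 ± 0.630 to 5.06 ± 0.599 CPM in wt (SD, n = 4), a log2 change of 4.98 ± 0.21 (SE, adjusted p = 2.9e-14). GAD1, which encodes glutamate decarboxylase, rose by 2.44 ± 0.27, the cell wall gene PIR3 by 2.26 ± 0.24, ARO10, which encodes a phenylpyruvate decarboxylase, by 2.06 ± 0.18, and the small heat shock gene HSP12 by 2.04 ± 0.44. The other 5 of the 10 largest rises were YNR068C, EMA17, HPA2, SYM1 and DFP3, between 2.07 ± 0.23 (DFP3) and 2.28 ± 0.27 (YNR068C). The largest fall was that of MET6, the methionine synthase gene (chromosome V, 339649 to 342233, minus strand), from 725 ± 189 to 69.7 ± 16.2 CPM, a log2 change of -3.36 ± 0.24 (adjusted p = 1.0e-09). The mating-type endonuclease gene HO changed by -2.62 ± 0.20, the glutamine synthetase gene GLN1 by -2.44 ± 0.20, the acetaldehyde dehydrogenase gene ALD6 by -2.26 ± 0.37, YKR075C by -2.23 ± 0.61 (adjusted p = 0.00578, and 0.0522 without replicate 3) and the S-adenosylmethionine synthetase gene SAM2 by -2.21 ± 0.16. In all, 4048 of 11776 features were called, 2176 higher and 1872 lower, and 1623 of the higher and 569 of the lower ones changed at least 2-fold. Among protein-coding genes 750 rose and 1575 fell, a balance that turned to 1205 higher and 1013 lower when protein-coding features were scaled and fitted alone. In 1998 of these 2325 genes the T60 and T0 libraries of dcp2-ideg did not overlap. Chance gives this in 2.86% of genes not chosen for a change, and these had been called, so the share describes them and is no further test. The balance rested on the scaling, which used no spike-in, so all changes are relative to the other poly(A) RNA. Under total count scaling 4461 features rose and 490 fell, so 90.1% of calls were rises against 53.8% with TMM, and the median of all features moved from 0.073 to 0.57. Changes relative to that median barely moved, and the protein-coding median lay -0.25 from it under both scalings.

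**Figure D2:**
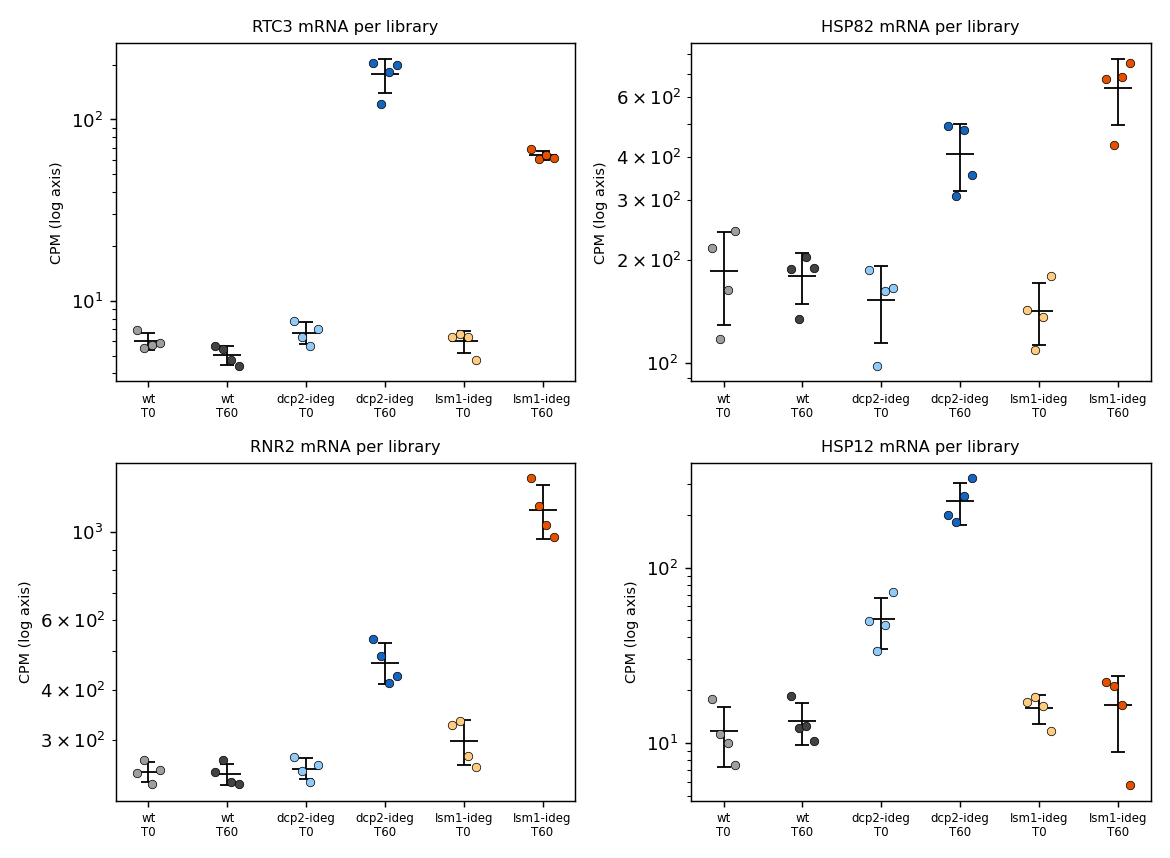
CPM on a log axis of RTC3, HSP82, RNR2 and HSP12 in each of the 24 libraries by strain and time, with points for libraries and bars for the mean ± SD of 4. RTC3 had 178 CPM in dcp2-ideg and 63.6 CPM in lsm1-ideg at T60, HSP82 and RNR2 were highest in lsm1-ideg at T60 with 637 and 1135 CPM, and HSP12 was highest in dcp2-ideg at T60 with 240 CPM.

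By gene list, the dcp2-ideg response beyond wt passed the camera test for 17 of 27 lists, 15 of them lower and 2 higher. Ribosomal protein genes were lower as a group, with a median log2 change of -1.18 and 133 of 138 members fallen and 0 risen (133 adjusted over the list alone, camera adjusted p = 1.1e-47, adjusted p = 0.0321 with an estimated correlation). RPL13B changed by -1.30 ± 0.12 and RPL7A, which has a near-identical copy and is uncertain, by -1.29. Relative to the median of all features this list lay at -1.25, and at -1.24 under total count scaling. Ribosomal protein genes took 24.7% of the counts in dcp2-ideg T0 replicate 4 and 15.3% to 16.01% in the other libraries of that group. Ribosome biogenesis genes had a median of -0.83, with 65 of 71 fallen and 0 risen (68 adjusted over the list alone, adjusted p = 6.8e-26, adjusted p = 0.0672 with an estimated correlation). They included DBP3 at -1.19 ± 0.14 and CBF5 at -0.95. Histone genes had a median of -1.40 with 8 of 8 fallen (8 adjusted over the list alone, adjusted p = 5.0e-07, adjusted p = 0.0321 with an estimated correlation). They included HHT2 at -1.19 ± 0.16 and HTB1 at -1.15. Genes of the G1 to S transition had a median of -1.27 with 9 of 10 fallen (9 adjusted over the list alone, adjusted p = 1.6e-07, adjusted p = 0.0672 with an estimated correlation). The replication clamp gene POL30 was at -2.18 ± 0.15 and the ribonucleotide reductase gene RNR1 at -1.65 ± 0.21. Of the a-cell genes, 5 of 7 fell (5 adjusted over the list alone, median -0.99, adjusted p = 3.6e-05, adjusted p = 0.0321 with an estimated correlation). BAR1 was at -1.27 ± 0.11 and the pheromone receptor gene STE2 at -0.88. For G2 and M genes, 3 of 9 fell (3 adjusted over the list alone, median -0.51, and -0.0080 under total count scaling). They were CDC20 at -0.73 ± 0.14, CLB2 at -0.61 and CDC5 at -0.51 (list adjusted p = 0.0402, adjusted p = 0.317 with an estimated correlation). All 3 lost their call under total count scaling, with adjusted p = 0.154 for CDC20, 0.571 for CLB2 and 0.982 for CDC5. The call of CLB2 was also lost without replicate 1 or 3, and that of CDC5 without replicate 3, at 10 CPM and among protein-coding features alone.

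Metabolic lists fell in dcp2-ideg beyond wt as well, relative to the other poly(A) RNA. The values below are with TMM. Total count scaling shifted features in dcp2-ideg upwards, with the protein-coding median at 0.32 in place of -0.18, so these falls are smaller or absent there. The glycolysis gene GPM1, for example, lost its call under that scaling (adjusted p = 0.0971). Glycolysis had 12 of 16 members fallen and 0 risen (12 adjusted over the list alone, median -0.71, adjusted p = 7.5e-06, adjusted p = 0.0846 with an estimated correlation). The hexokinase gene HXK2 was at -1.39 ± 0.12, PGI1 at -1.003 and ADH1 at -0.96. For the nuclear-encoded respiratory chain, 27 of 38 fell and 0 rose (30 adjusted over the list alone, median -0.77, adjusted p = 5.5e-11, adjusted p = 0.0672 with an estimated correlation). ATP3 was at -1.20 ± 0.13 and SDH3 at -1.09. Amino acid biosynthesis genes had 28 of 43 fallen and 3 risen (28 fell adjusted over the list alone, median -0.65, adjusted p = 8.1e-09, adjusted p = 0.0659 with an estimated correlation). ARO2 was at -1.29 ± 0.12 and ASN1 at -1.09. In the sulfur list 13 of 22 fell and 1 rose (15 fell and 1 rose adjusted over the list alone, median -0.84, adjusted p = 4.3e-07, adjusted p = 0.0321 with an estimated correlation). MET2 was at -2.13 ± 0.24, SAM1 at -1.72 ± 0.15 and MMP1 at -1.78. Of the phosphate starvation genes, 11 of 13 fell and 1 rose (11 fell adjusted over the list alone, median -0.80, adjusted p = 0.000395, adjusted p = 0.0922 with an estimated correlation). The polyphosphate polymerase genes VTC3 and VTC1 were at -1.15 ± 0.15 and -0.84. For ergosterol synthesis, 16 of 24 fell and 0 rose (17 adjusted over the list alone, median -0.65, adjusted p = 2.4e-10, adjusted p = 0.0041 with an estimated correlation). ERG11 was at -1.28 ± 0.12 and ERG3 at -1.40 ± 0.13. The iron starvation list was mixed, with 11 of 20 fallen and 2 risen (11 fell adjusted over the list alone, median -0.52, adjusted p = 0.0274, adjusted p = 0.317 with an estimated correlation). The ferroxidase gene FET3 changed by -1.79 ± 0.27 and the permease gene FTR1 by -1.20, while the reductase genes FRE2 and FRE3 rose by 1.46 ± 0.16 and 1.17.

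The 2 lists that rose in dcp2-ideg beyond wt were the general stress response and meiosis. In the general stress response 24 of 36 rose and 0 fell (27 adjusted over the list alone, median 1.10, adjusted p = 1.5e-09, adjusted p = 0.0672 with an estimated correlation). Its members with the smallest adjusted p were RTC3, GAD1, the glycogen synthase gene GSY2 at 1.91 ± 0.21 and ALD3 at 1.83 ± 0.17. For meiosis genes 12 of 29 rose and 0 fell (12 adjusted over the list alone, median 0.57, adjusted p = 0.00465, adjusted p = 0.0321 with an estimated correlation). The meiotic kinase gene IME2 was at 1.62 ± 0.22 and REC104 at 1.46. Decapping and 5'-3' decay factors had 7 of 19 fallen and 2 risen (9 fell and 2 rose adjusted over the list alone, median -0.40, adjusted p = 0.0488, adjusted p = 0.195 with an estimated correlation). Its median turned to 0.092 under total count scaling. The decapping subunit gene DCP1 changed by -0.92 ± 0.21 (adjusted p = 0.154 under total count scaling), and DCS1, which encodes a cap-scavenging enzyme, rose by 0.66 ± 0.15. Deadenylation and exosome factors had 12 of 27 fallen and 0 risen (14 adjusted over the list alone, median -0.41, adjusted p = 2.1e-05, adjusted p = 0.0912 with an estimated correlation). The exosome genes RRP46 and MTR3 were at -0.83 ± 0.15 and -0.67. Under total count scaling both lost their call (adjusted p = 0.137 and 0.299), and the list median turned to 0.083. The other 10 lists did not pass. NMD-sensitive mRNAs had a median of 0.24 with 5 of 15 risen (adjusted p = 0.0572), and the model mRNAs a median of -0.54 with 2 of 6 fallen (adjusted p = 0.0682). Nitrogen catabolite repression genes had a median of 0.46 with 6 of 21 risen and 1 fallen (adjusted p = 0.0545, and 0.0427 with the replicate number as a block). Heat shock factor targets had a median of 0.096 with 7 of 23 risen and 3 fallen (7 and 4 adjusted over the list alone, adjusted p = 0.35). Medians were 0.41 for alternative carbon source use (8 risen and 5 fallen of 33, adjusted p = 0.302), 0.55 for the galactose regulon (4 risen and 1 fallen of 10, adjusted p = 0.211) and 0.11 for drug efflux (4 risen and 4 fallen of 20, adjusted p = 0.675, with a mean of the other sign). They were -0.081 for NMD factors (0 of 5 called by edgeR, adjusted p = 0.966, with a mean of the other sign), 0.061 for M to G1 genes (0 of 9 called by edgeR, adjusted p = 0.754) and 0.41 for alpha-cell genes (1 of 4 risen, adjusted p = 0.535).

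**Figure D3:**
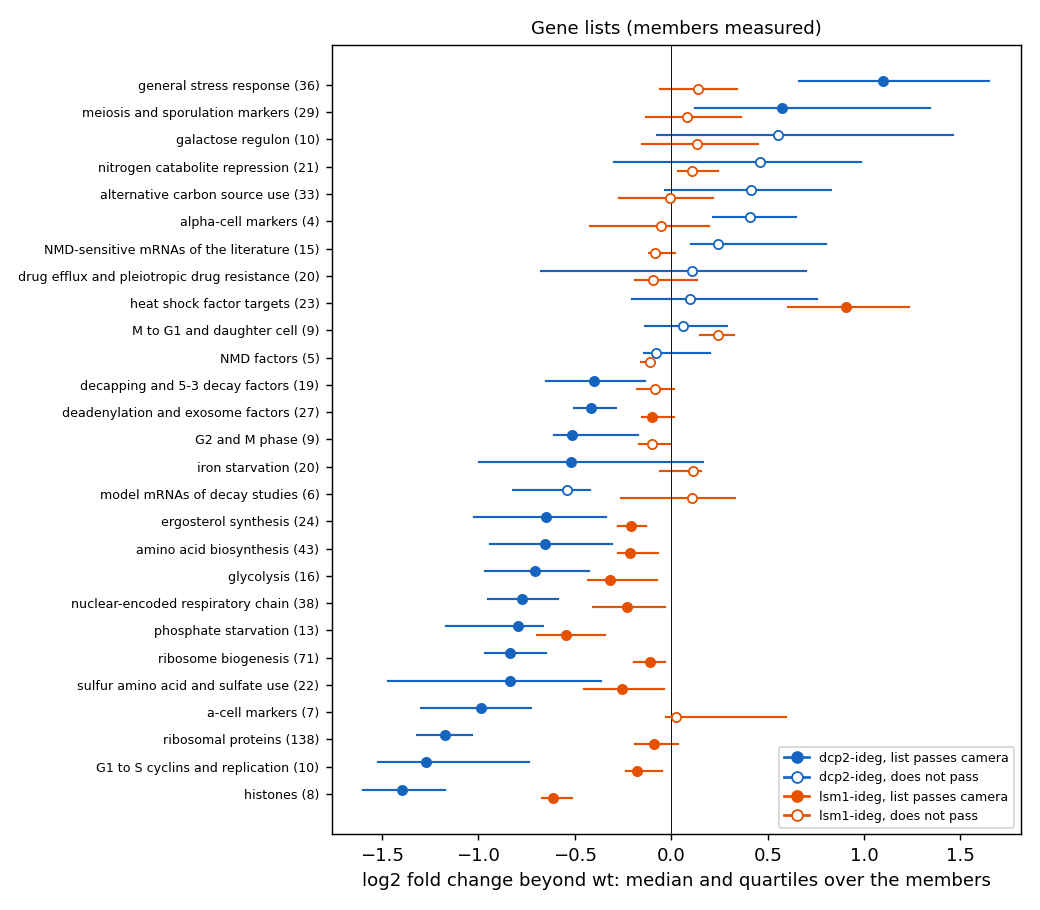
Median log2 change beyond wt of each of the 27 gene lists (horizontal axis, lines for quartiles) in dcp2-ideg and lsm1-ideg, with filled points for lists that passed the camera test. Ribosomal protein genes lay at -1.18 in dcp2-ideg and -0.087 in lsm1-ideg, heat shock factor targets at 0.096 and 0.91, and under total count scaling the dcp2-ideg medians shifted up, with decapping factors at 0.092 and deadenylation and exosome factors at 0.083.

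XUTs and SUTs rose in dcp2-ideg beyond wt. XUTs, which accumulate without the 5'-3' exonuclease Xrn1, had a median log2 change of 0.92, with 667 of 1657 risen and 21 fallen (Fisher's exact test for risen members against all other features, adjusted p = 1.3e-112). Over the 766 XUTs alone on their strand the median was 0.85, with 243 risen and 11 fallen (Fisher adjusted p = 8.7e-42 against other features alone). SUTs had a median of 0.93, with 385 of 836 risen and 11 fallen (adjusted p = 2.1e-80). Over the 169 SUTs alone on their strand the median was only 0.32, with 37 risen and 4 fallen (Fisher adjusted p = 0.00695). Fisher's test takes features as independent, which overlapping features that share reads are not, so the p-values over all members are too small. Relative to the median of all features, XUTs lay at 0.85 and SUTs at 0.86 under both scalings. CUTs, which the nuclear exosome degrades, had a median of 0.43 (121 of 907 risen, 30 fallen), the CUT_GIM set 0.22 (149 of 1254 risen, 116 fallen), dubious open reading frames 0.12 (59 of 732 risen, 64 fallen) and introns -0.26 (13 of 260 risen, 31 fallen). CUTs and the CUT_GIM set had fewer risen members than other features (adjusted p = 3.4e-05 and 7.3e-11) and fewer fallen ones as well (adjusted p = 1.2e-35 and 1.6e-12). In lsm1-ideg beyond wt the medians were 0.17 for XUTs (2 of 1657 risen), 0.16 for SUTs (0 of 836 called by edgeR), 0.17 for CUTs and 0.11 for introns. The difference between the strains' responses was itself called for 543 XUTs that were higher in dcp2-ideg and 25 that were lower (median 0.78), and for 332 SUTs higher and 17 lower (median 0.71).

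**Figure D4:**
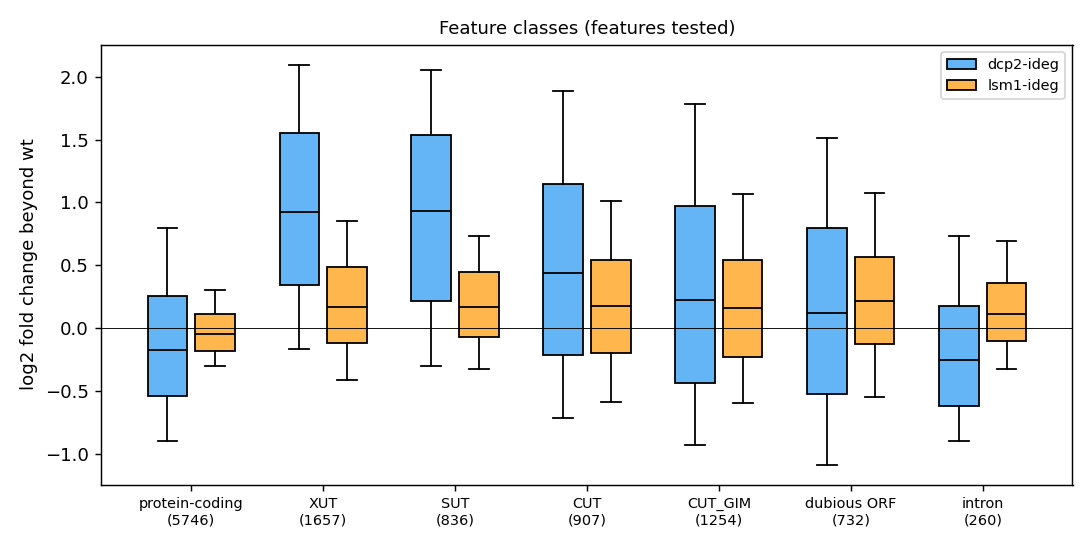
Boxplots of the log2 change beyond wt of each feature class in dcp2-ideg and lsm1-ideg (box for quartiles, line for the median, whiskers from the 10th to the 90th percentile). XUTs and SUTs had medians of 0.92 and 0.93 in dcp2-ideg and 0.17 and 0.16 in lsm1-ideg, while protein-coding genes had -0.18 in dcp2-ideg (0.32 under total count scaling) and -0.044 in lsm1-ideg (0.0086 under total count scaling).

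The second comparison asked the same of lsm1-ideg, where few features were called beyond wt. In simulated data 23 of 100 features changed 2-fold were recovered in this comparison, so few calls do not show that few RNAs changed. Loss of the tagged proteins was not measured here, and selection on poly-T beads left out RNA without a poly(A) tail. RTC3 rose from 5.997 ± 0.849 to 63.6 ± 3.44 CPM (SD, n = 4), a log2 change of 3.66 ± 0.21 (SE, adjusted p = 2.7e-11). HSP82, the gene of the chaperone Hsp90 (chromosome XVI, 96397 to 98677, minus strand), rose from 142 ± 29.2 to 637 ± 140 CPM, by 2.21 ± 0.32 (adjusted p = 0.00052). RNR2, the small subunit gene of ribonucleotide reductase (chromosome X, 392341 to 393741, plus strand), rose from 297 ± 38.7 to 1135 ± 174 CPM, by 1.95 ± 0.16 (adjusted p = 3.7e-08). SSA1, an Hsp70 gene with a near-identical copy and therefore uncertain, rose by 1.52 ± 0.19, and AHA1 and STI1, which encode Hsp90 co-chaperones, by 1.28 ± 0.16 and 1.19 ± 0.22. TMC1 rose by 1.38 ± 0.21 (adjusted p = 0.00121), YNR068C by 1.36 ± 0.27 (adjusted p = 0.0238), the vacuolar protease gene PRB1 by 1.36 ± 0.25 (adjusted p = 0.0101) and LIA1, which encodes deoxyhypusine hydroxylase, by 1.12 ± 0.16. The 3 falls were those of the cell wall gene CWP1, from 107 ± 31.1 to 27.9 ± 5.20 CPM, by -2.31 ± 0.40 (adjusted p = 0.0047), the glycerol phosphatase gene GPP1, by -1.02 ± 0.21 (adjusted p = 0.0353), and SAM2, by -0.78 ± 0.15 (adjusted p = 0.0246). Part of the CWP1 value came from wt, where it changed by 0.37. CWP1 had 204 CPM in wt T60 replicate 3, a library that stood apart, and 76.9 to 105 CPM in the other wt T60 libraries. In all, 25 features were called, 22 higher and 3 lower, of which 16 and 3 were protein-coding, and 903 had an unadjusted p under 0.05. In 19 of the 19 genes the T60 and T0 libraries of lsm1-ideg did not overlap. The count moved with single libraries, to 16 without lsm1-ideg T60 replicate 3 and 16 without wt T0 replicate 4, and DESeq2 called 101. It rose to 68 without replicate 4 of every group, and to 101 without the dcp2-ideg pair of number 4, which this comparison does not use. Against wt at T60 only, which includes differences present at T0, it was 462. Without replicate 1 of every group only 6 were called, and HSP82 (adjusted p = 0.0575), LIA1 (0.0536), TMC1 (0.178), PRB1 (0.118), STI1 (0.176) and CWP1 (0.0575) were not among them. PRB1, STI1 and CWP1 were not called without replicate 2 or 3 of every group either, with adjusted p between 0.0904 and 0.388. The call of GPP1 was lost without any 1 of the 16 libraries compared except lsm1-ideg T60 replicate 1 and wt T60 replicate 4 (adjusted p between 0.0553 and 0.117). That of SAM2 was lost except without those 2, wt T0 replicate 1, wt T60 replicate 2 or lsm1-ideg T0 replicate 4 (0.0576 to 0.0874). That of YNR068C was lost without wt T0 replicate 1 or 4, wt T60 replicate 2, lsm1-ideg T0 replicate 1, 2 or 4, or lsm1-ideg T60 replicate 3 (0.0556 to 0.0752).

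Among the lists, heat shock factor targets rose in lsm1-ideg beyond wt. They had a median log2 change of 0.91, with 7 of 23 members risen and 0 fallen (18 risen adjusted over the list alone, camera adjusted p = 5.3e-33, adjusted p = 0.00251 with an estimated correlation). They included HSP82, SSA1, AHA1 and the Hsp70 gene SSA4 at 1.02 ± 0.17 (adjusted p = 0.118 without replicate 1 and 0.267 without replicate 3). The other 11 lists that passed were lower, and apart from SAM2 no member was called over all features. Phosphate starvation genes had a median of -0.54 (4 of 13 fallen adjusted over the list alone, adjusted p = 3.6e-08, adjusted p = 0.0283 with an estimated correlation). The phosphatase gene PHO5 was at -1.09 ± 0.26 (adjusted p = 0.0798). Histone genes had a median of -0.61 (1 of 8 fallen adjusted over the list alone, adjusted p = 1.5e-07, adjusted p = 0.0283 with an estimated correlation) and ergosterol genes of -0.21 (adjusted p = 4.0e-07, adjusted p = 0.0143 with an estimated correlation). The calls of the remaining 8 were lost with an estimated correlation. They were glycolysis at -0.32 (4 of 16 fallen adjusted over the list alone, adjusted p = 0.284 with an estimated correlation), the respiratory chain at -0.23 (2 of 38 adjusted over the list alone, adjusted p = 0.35 with an estimated correlation), ribosomal proteins at -0.087 (adjusted p = 0.657 with an estimated correlation), ribosome biogenesis at -0.11 (adjusted p = 0.617 with an estimated correlation), amino acid biosynthesis at -0.21 (adjusted p = 0.136 with an estimated correlation), the sulfur list at -0.25 (2 of 22 adjusted over the list alone, adjusted p = 0.0984 with an estimated correlation), G1 to S genes at -0.18 (adjusted p = 0.563 with an estimated correlation) and deadenylation and exosome factors at -0.10 (adjusted p = 0.515 with an estimated correlation). The general stress response had a median of 0.14 with RTC3 as its 1 called member (adjusted p = 0.183). The decay-related lists did not pass, with medians of -0.084 for decapping factors (adjusted p = 0.316), -0.11 for NMD factors (adjusted p = 0.215), -0.083 for NMD-sensitive mRNAs (adjusted p = 0.316) and 0.11 for the model mRNAs (adjusted p = 0.78). Nor did alternative carbon source use (-0.0081, 1 fallen adjusted over the list alone), iron starvation (0.11), nitrogen catabolite repression (0.11, adjusted p = 0.0542, 1 risen adjusted over the list alone), drug efflux (-0.093), the galactose regulon (0.14), G2 and M (-0.10), M to G1 (0.24, adjusted p = 0.0803), a-cell (0.025, 1 risen and 1 fallen adjusted over the list alone), alpha-cell (-0.051) and meiosis genes (0.083).

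The third comparison tested the dcp2-ideg response against the lsm1-ideg response directly. GAD1 was higher in the dcp2-ideg response by 2.52, HSP12 by 2.18, EMA17 by 2.07, ARO10 by 2.04 ± 0.18 (adjusted p = 4.1e-08) and the mannosyltransferase gene MNT4 by 1.87 ± 0.15 (adjusted p = 1.1e-08), and PPT2, ATG29, DFP3, SYM1 and PIR3 differed by 1.82 to 1.99. HO was lower by -2.57 ± 0.20 (adjusted p = 1.1e-08), MET6 by -2.34 ± 0.24 (adjusted p = 3.6e-07), the a-factor gene MFA1 by -2.10 ± 0.25, YKR075C by -1.998 ± 0.61 (adjusted p = 0.0519 under total count scaling, 0.0706 without replicate 1 and 0.0853 without replicate 3), FET3 by -1.93 ± 0.27 and MET2 by -1.87 ± 0.24. RTC3 rose in both strains and more in dcp2-ideg, by 1.32 ± 0.20 (adjusted p = 2.8e-05). The difference for HSP82 was -0.75 ± 0.32 (adjusted p = 0.0798). In all, 3361 features differed, 1793 higher and 1568 lower in the dcp2-ideg response, of which 635 and 1226 were protein-coding. The T60 and T0 libraries of dcp2-ideg did not overlap in 1668 of these 1861 genes. Under total count scaling 3726 were higher and 370 lower, 91.0% against 53.3% with TMM, with the median of all features at 0.45 in place of 0.0067.

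Heat shock factor targets were lower in the dcp2-ideg than in the lsm1-ideg response, with a median of -0.83 and 12 of 23 lower and 2 higher (14 lower and 3 higher adjusted over the list alone, camera adjusted p = 8.6e-06, adjusted p = 0.148 with an estimated correlation). Among them the Hsp90 gene HSC82 differed by -1.21 ± 0.16 and FES1 by -1.08, while the polyubiquitin gene UBI4 was higher by 1.17 ± 0.19. NMD-sensitive mRNAs were higher, with a median of 0.36 and 5 of 15 higher (adjusted p = 0.00591, adjusted p = 0.0321 with an estimated correlation). They included DAL7 at 1.497 ± 0.25, STN1 at 1.26, EST2 at 1.10 ± 0.17 and EST3 at 0.83. Ribosomal protein genes had a median of -1.10 with 135 of 138 lower and 1 higher (adjusted p = 2.4e-51, adjusted p = 0.0314 with an estimated correlation), and ribosome biogenesis genes of -0.73 with 61 of 71 lower (68 adjusted over the list alone, adjusted p = 0.0796 with an estimated correlation). The general stress response had a median of 0.80 with 22 of 36 higher and 0 lower (27 adjusted over the list alone, adjusted p = 5.6e-10, adjusted p = 0.0796 with an estimated correlation), and meiosis genes of 0.80 with 9 of 29 higher (adjusted p = 0.0032, adjusted p = 0.0202 with an estimated correlation). For a-cell genes 6 of 7 were lower (7 adjusted over the list alone, adjusted p = 0.013 with an estimated correlation), for the model mRNAs 4 of 6 (adjusted p = 0.0257, adjusted p = 0.236 with an estimated correlation, with PGK1 at -0.66, and adjusted p = 0.398 for it under total count scaling), and for histones 7 of 8 (8 adjusted over the list alone, adjusted p = 0.000305, adjusted p = 0.105 with an estimated correlation). Under total count scaling the histone genes HHT1 (adjusted p = 0.0645), HHT2 (0.312) and HTB2 (0.244) lost their call. Of the model mRNAs, RPS28B lost its call under that scaling, with limma-voom and without any of several single libraries (adjusted p up to 0.395 over all settings). MFA2 lost its call without replicate 2 of every group (0.0813). Ergosterol genes had a median of -0.42, which turned to 0.034 under total count scaling (12 of 24 lower, 13 adjusted over the list alone, adjusted p = 2.6e-07, adjusted p = 0.013 with an estimated correlation). In total 17 lists passed, 14 lower and 3 higher. The other 7 included glycolysis (9 lower, and 9 lower and 1 higher adjusted over the list alone, adjusted p = 0.182 with an estimated correlation), the respiratory chain (17 lower, 19 adjusted over the list alone, adjusted p = 0.141 with an estimated correlation) and amino acid biosynthesis (20 lower and 2 higher, 23 and 2 adjusted over the list alone, adjusted p = 0.141 with an estimated correlation). They also included the sulfur list (10 lower and 1 higher, adjusted p = 0.0796 with an estimated correlation), G1 to S genes (9 lower, adjusted p = 0.0868 with an estimated correlation), deadenylation and exosome factors (median -0.36, and 0.088 under total count scaling, adjusted p = 0.17 with an estimated correlation) and iron starvation (9 lower and 2 higher, 10 and 2 adjusted over the list alone, median -0.41, and 0.025 under total count scaling, adjusted p = 0.265 with an estimated correlation).

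The responses of both degron strains beyond wt overlapped. Of the 25 features called in lsm1-ideg, 13 also rose and 2 also fell in dcp2-ideg, RTC3 and YNR068C among the risen and SAM2 among the fallen, against 4.07 and 0.477 for independent lists. In 20 simulations without effects at most 0 were called in both, which sets no chance level for lists of this length. With the wt libraries split between the comparisons, 6 features were called in both one way round and 7 the other, against 1.46 and 1.19 risen for independent lists, and the log2 changes correlated with r = 0.0834 and 0.177 (covariances 0.0685 and 0.129). Across all features the log2 changes correlated with r = 0.455, and unchanged groups sharing the wt libraries gave 0.501. The covariance was 0.246 beside a simulated 0.117, a difference of 0.129, and features are not independent replicates. The changes within each strain share no library, and there 87 features rose and 77 fell in both strains, against 36.8 and 20.6 for independent lists, with r = 0.341 and a covariance of 0.130.

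**Figure D5:**
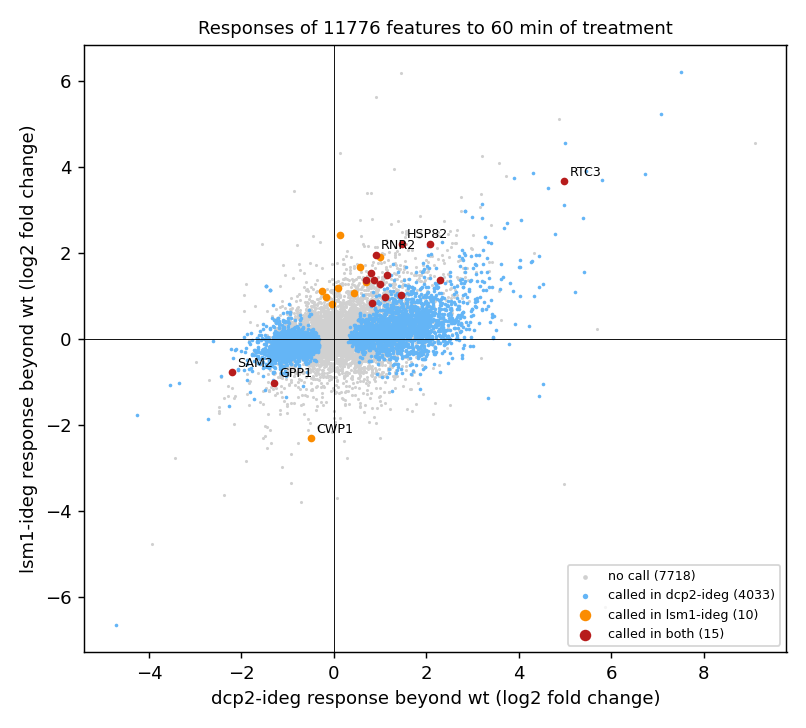
Log2 change beyond wt in dcp2-ideg (horizontal axis) against that in lsm1-ideg (vertical axis), with a point for each of the 11776 features tested. RTC3 lies at 4.98 and 3.66, and the cloud is wider along the dcp2-ideg axis, where 4048 features were called against 25 in lsm1-ideg.

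Features that changed within dcp2-ideg were then followed in lsm1-ideg, in libraries not used to choose them. The 3286 features that rose in dcp2-ideg, by a median of 1.24, had a median of 0.20 from T0 to T60 in lsm1-ideg and 0.048 in wt, and 77.3% of them had the same sign in lsm1-ideg against 59.0% in wt. The camera test in lsm1-ideg gave p = 7.0e-16, and p = 6.5e-06 with an estimated correlation. The 2816 that fell in dcp2-ideg, by a median of -0.71, had medians of -0.13 in lsm1-ideg and -0.032 in wt, with 78.9% of the same sign in lsm1-ideg against 59.7% in wt (p = 8.2e-28, and p = 3.4e-07 with an estimated correlation). The 970 XUTs that rose in dcp2-ideg had medians of 1.47 there, 0.27 in lsm1-ideg and 0.082 in wt.

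Within dcp2-ideg, T60 against T0, RTC3 rose by 4.73 ± 0.16, GAD1 by 2.45 ± 0.20, EMA17 by 2.41, PIR3 by 2.30 and HSP12 by 2.24, and MET6 changed by -3.38 ± 0.18, HO by -2.67 ± 0.15, GLN1 by -2.46, URA3 by -2.21 ± 0.23 and SAM2 by -2.14 ± 0.11. Altogether 6102 features were called, 3286 higher and 2816 lower, with 1120 and 2245 among protein-coding genes, and under total count scaling 6316 were higher and 803 lower (88.7% against 53.9% higher). Of the 3365 protein-coding genes, 2385 had no overlap between T0 and T60 libraries. By list, 135 of 138 ribosomal protein genes fell and 2 rose (median -1.15), 71 of 71 ribosome biogenesis genes fell (median -0.87), 8 of 8 histone genes fell (median -1.33) and 30 of 36 general stress genes rose (31 adjusted over the list alone, median 1.05). With an estimated correlation 3 of the 18 lists that passed were still called, namely ergosterol, a-cell and meiosis genes. XUTs had a median of 0.99, with 970 risen and 41 fallen.

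Within lsm1-ideg, T60 against T0, RTC3 rose by 3.40 ± 0.15, HSP82 by 2.17 ± 0.23, RNR2 by 1.93 ± 0.12, TMC1 by 1.72 ± 0.15 and BTN2 by 1.56 ± 0.30 (adjusted p = 0.00408). CWP1 changed by -1.94 ± 0.29, URA3 by -1.29 ± 0.23, ALD6 by -1.18 ± 0.26 (adjusted p = 0.0150), MET6 by -1.04 ± 0.17 (adjusted p = 0.00082) and GPP1 by -0.98 ± 0.15. Heat shock factor targets rose in 18 of 23 cases and fell in 0 (22 adjusted over the list alone, median 0.81, adjusted p = 2.4e-39, adjusted p = 0.000925 with an estimated correlation). Of the histone genes 3 of 8 fell (5 adjusted over the list alone, median -0.51, adjusted p = 0.0253 with an estimated correlation), of the glycolysis genes 3 of 16 (8 adjusted over the list alone, median -0.33, adjusted p = 0.0865 with an estimated correlation), with ADH1 at -0.65 ± 0.10, and of the ergosterol genes 1 of 24 (8 adjusted over the list alone, median -0.24, adjusted p = 0.00144 with an estimated correlation). Without T60 replicate 4 alone, the calls of the histone genes HTB1 (adjusted p = 0.0515) and HTB2 (0.112) were lost. So were those of the glycolysis genes PGI1 (0.0517) and HXK2 (0.0677). The calls of HTB2 and HXK2 were also lost without several other single libraries. XUTs had a median of 0.23 with 24 risen and 0 fallen, and SUTs of 0.22 with 15 risen and 1 fallen. In all 218 features were called, 132 higher and 86 lower, and 208 and 39 under total count scaling (84.2% against 60.6% higher). In 139 of the 140 protein-coding genes called the groups did not overlap. The count was 121 and 132 without T0 replicates 1 and 2, 118 without T60 replicate 3, 130 and 101 without T0 and T60 replicates 4, and 1034 when only these 8 libraries were fitted. The call of ALD6 was lost without T60 replicate 1 or 3 or T0 replicate 2 or 3 (adjusted p between 0.0598 and 0.0704). Without replicate 1, 2 or 3 of every group ALD6 (0.116 to 0.203) and URA3 (0.0533 to 0.0614) were not called, nor was BTN2 without replicate 1 or 3 (0.118 and 0.107) or MET6 without replicate 2 (0.0513).

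In wt, T60 against T0, edgeR called 0 features, 388 had an unadjusted p under 0.05, and DESeq2 called 1. The phosphate starvation list had a median of 0.20 (adjusted p = 0.0188) and the iron starvation list of -0.19 (adjusted p = 0.00729), with adjusted p = 0.98 for both with an estimated correlation and 0 members called by edgeR.

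At T0 the degron strains already differed from wt. URA3, which encodes orotidine 5'-phosphate decarboxylase, was at 0.444 ± 0.157 CPM in wt, 25.8 ± 8.96 in dcp2-ideg (12.4 in replicate 4) and 36.3 ± 4.39 in lsm1-ideg, log2 differences of 5.85 ± 0.29 (adjusted p = 1.1e-12) and 6.35 ± 0.30. RME1, a repressor of meiosis, was at 47.0 ± 4.70 CPM in wt, 0.517 ± 0.215 in dcp2-ideg and 0.144 ± 0.204 in lsm1-ideg, differences of -6.51 ± 0.40 and -8.31 ± 0.46. In dcp2-ideg the other largest differences were those of YLR154C-H at 3.11 ± 0.42 (near-identical copies, uncertain), HSP12 at 2.12 ± 0.32, MET2 at 1.45 ± 0.17 and the riboflavin synthesis gene RIB4 at 1.25 ± 0.13, and of COS8 at -2.82 ± 0.19, TIR1 at -1.36 ± 0.28 (adjusted p = 0.0132), YPS3 at -1.19 ± 0.19 and NCA3 at -1.13 ± 0.21. In lsm1-ideg they were those of RIB4 at 1.24 ± 0.13, TIM9 at 1.01 ± 0.16, URA1 at 1.00 ± 0.15 and IMD2 at 0.90 ± 0.10, and of NCA3 at -1.76 ± 0.21, YRO2 at -1.47 ± 0.28, YGP1 at -1.41 ± 0.15 and OCH1 at -0.61 ± 0.093. Genes of the sulfur list were higher in dcp2-ideg, with 6 of 22 called (14 adjusted over the list alone, median 0.42, adjusted p = 1.8e-14, adjusted p = 0.00535 with an estimated correlation), and in lsm1-ideg, with 1 called (10 adjusted over the list alone, median 0.34, adjusted p = 0.0144 with an estimated correlation). Phosphate starvation genes were higher in lsm1-ideg, with 1 of 13 called (6 adjusted over the list alone, median 0.39, adjusted p = 0.0144 with an estimated correlation). The other lists that passed lost their call with an estimated correlation. In dcp2-ideg they were ribosomal proteins at 0.21 (adjusted p = 0.731 with an estimated correlation), the respiratory chain at 0.23 (adjusted p = 0.712 with an estimated correlation), phosphate starvation at 0.20 (4 risen adjusted over the list alone) and G1 to S genes at -0.18 (adjusted p = 0.697 with an estimated correlation for both). In lsm1-ideg they were ribosomal proteins at 0.074 (adjusted p = 0.752 with an estimated correlation), the respiratory chain at -0.12 (1 fallen adjusted over the list alone, adjusted p = 0.652 with an estimated correlation), amino acid biosynthesis at 0.13 (adjusted p = 0.35 with an estimated correlation), iron starvation at -0.20 (adjusted p = 0.163 with an estimated correlation) and M to G1 genes at 0.16 (2 risen adjusted over the list alone, adjusted p = 0.67 with an estimated correlation). In dcp2-ideg 97 features were called, 69 higher and 28 lower, and 63 without wt T0 replicate 2 or 64 without wt T0 replicate 4. TIR1 was not called without wt T0 replicate 2 (adjusted p = 0.0835) or without replicate 1, 2 or 3 of every group (0.0866 to 0.139), nor NCA3 without replicate 1 (0.131). With only these 8 libraries fitted, TIR1 (0.353), YPS3 and NCA3 (0.0512 for both) were not called. In lsm1-ideg 41 were called, 23 higher and 18 lower, and YRO2 was not called without lsm1-ideg T0 replicate 3 (adjusted p = 0.0632) or without replicate 2 or 3 of every group (0.233 and 0.190). Calls were also lost without replicate 1 for URA1 (0.0797) and OCH1 (0.0721) and without replicate 3 for TIM9 (0.119). In 54 of 55 and 24 of 24 protein-coding genes called, the groups did not overlap.

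Across 5594 of 5746 protein-coding genes, abundance and codon content were compared with each response, where genes are not independent replicates. More abundant mRNAs had lower changes beyond wt in dcp2-ideg, with a rank correlation of -0.569, and in lsm1-ideg, with -0.279. Codon content was the mean log relative adaptiveness of a gene's codons, with weights from the ribosomal protein genes, which were then left out. Its rank correlation with the change was -0.366 in dcp2-ideg and -0.285 in lsm1-ideg, and given abundance the partial rank correlations were -0.0982 and -0.171. From T0 to T60 within each strain these partial correlations were -0.0506 in dcp2-ideg, -0.100 in lsm1-ideg and 0.157 in wt, where edgeR called 0 features. The values beyond wt thus hold a part from wt. The partial rank correlation with coding length given abundance was 0.205 in dcp2-ideg and -0.0510 in lsm1-ideg beyond wt. Within strain it was 0.163 in dcp2-ideg, -0.195 in lsm1-ideg and -0.156 in wt.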

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

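All tests of explanations and the counts over other splits in this part were chosen after the results they concern had been seen. Within each group of 4 libraries, 78 sets of values were examined for a library far from the other 3, and 10 were found, where chance gives about 1 in 20 groups, or 3.9 here. Ribosomal protein genes took 24.7% of the counts in dcp2-ideg T0 replicate 4 (others 15.3% to 16.01%), 14.6% in dcp2-ideg T60 replicate 4 (others 10.5% to 11.2%) and 16.03% in lsm1-ideg T0 replicate 4 (others 16.2% to 16.3%). The URA3 level was 12.4 CPM in dcp2-ideg T0 replicate 4 (others 29.0 to 31.4) and 42.8 CPM in lsm1-ideg T0 replicate 3 (others 33.6 to 34.8). RME1 had 0.449 CPM in lsm1-ideg T0 replicate 3 (others 0.0393 to 0.0455). RTC3 had 4.73 CPM in lsm1-ideg T0 replicate 4 (others 6.31 to 6.58), and COS8 had 39.5 CPM in wt T60 replicate 1 (others 29.0 to 30.3). The total of dcp2-ideg T60 replicate 3 was 41.8 M counts (others 54.1 to 56.2 M), and the TMM factor of lsm1-ideg T0 replicate 1 was 0.899 (others 0.927 to 0.933).

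Tests of a difference between strains gave 4048 features whose response differed between dcp2-ideg and wt, 25 between lsm1-ideg and wt and 3361 between dcp2-ideg and lsm1-ideg. Within each strain, 17 features were called in both degron strains in opposite directions, and the difference of responses was called for all 17. Their choice by opposite calls nearly ensured this, so it is no further test. The opposite direction rested on the TMM scaling, since under total count scaling 2 of the 17 were still opposite and called in both.

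The first pattern weighed is the rise of XUTs and SUTs in dcp2-ideg. Reads of genes overlapping the XUTs on their strand are argued against as the whole cause, since the median over XUTs alone on their strand was 0.853 (SD of the medians over replicates 0.0890), and for SUTs alone it was 0.317 (SD 0.112) in place of 0.931, so part of the SUT value stays open. Reads leaking at a constant share from coding genes on the opposite strand are argued against. The 1250 coding genes opposite XUTs had a median of 0.0228 (SD 0.0721) where the XUTs themselves had 0.811. A larger share of wrong-strand reads in the treated libraries would leave the genes unchanged. That was not tested, as the strand check used means over all 24 libraries. For genomic DNA in the treated libraries, the 240 introns alone on their strand showed no rise, with a median of -0.225 (SD 0.298). Introns also hold reads of unspliced transcripts, and 1575 protein-coding genes fell in this comparison, so the introns do not decide on genomic DNA. For the XUTs, the degron for DCP2 that the design names may account for the rise, which remains a hypothesis found and tested on the same data. Genomic DNA and a changed share of wrong-strand reads are left open.

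The second pattern is the rise of genes in both degron strains beyond wt. The shared wt libraries are argued against as the whole cause, since within each strain, where no library is shared, 87 features rose in both against 36.8 for independent lists. Without the libraries that stand apart, dcp2-ideg T0 replicate 4 and wt T60 replicate 3, there were 31 features in both in place of 15. Features called in both thus did not vanish without these libraries. The calls also lengthened there, from 25 to 47 in lsm1-ideg and from 4048 to 4679 in dcp2-ideg. No chance level was computed for the 31, so the larger count decides nothing further on these libraries. For the added compounds acting on any strain, the median of -0.0682 in wt over the 13 risen features (1.36 in lsm1-ideg) decides nothing, as these were chosen after the wt change was subtracted. Over the 87 features that rose within both strains, chosen without wt, the compounds are argued against by a median of 0.0518 in wt (spread 0.266) beside 0.912 in lsm1-ideg. A response to losing either decay factor may underlie the overlap, as may a response to any induced degron, which the design has no strain to test.

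The third pattern is dcp2-ideg T0 replicate 4, which stood apart from its group. RNA of treated dcp2-ideg cells is argued against, since the levels of 165 strongly risen features would need a median share of 1.68% (spread 1.40), and wt RNA is argued against, since the RME1 level would need 0.434%. A fault of this library alone is argued against, since its deviation from the group correlated across features with that of the T60 library of number 4 at 0.632. A difference between the cultures or handling of number 4 may remain, and no biological explanation was tested.

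For each count of called features, the libraries compared were also split in other ways and fitted without the other groups. For the dcp2-ideg response beyond wt, 2 of 100 splits, the real one included, called as many features as the real 3515 (highest other 4462), and for the dcp2-ideg against the lsm1-ideg response 4 of 100 (real 3288, highest other 3721). For the lsm1-ideg response beyond wt 5 of 100 splits called as many as the real 55, and the highest other split called 409, several times the real count, which points to a structure of the samples. All other splits as large, 1 for dcp2-ideg beyond wt, 3 between the strains and 4 for lsm1-ideg beyond wt, kept the T60 libraries of each strain together. With T60 libraries mixed the highest counts were 1, 6 and 6. The shares thus depended on how many splits of that kind were drawn (2, 5 and 5 with the real one), so for these 3 comparisons the count neither excluded chance nor showed it. For dcp2-ideg T0 against wt T0, 1 of 35 splits called as many (real 25, highest other 0), and for lsm1-ideg T0 against wt T0 also 1 of 35 (50 and 1). That is the smallest share these splits can give, and it concerns only the grouping of these samples. The samples may not be separate cultures, so chance differences between cultures are not excluded by it. For wt T60 against T0 the real count was 0, so 35 of 35 splits called as many (highest other 0), and the count says nothing about chance there. For dcp2-ideg T60 against T0, 1 of 35 splits called as many (real 5285, highest other 0). The numbers were taken to pair these libraries, and besides the real split 7 others part all 4 pairs (highest count 0), too few for a share under 0.05 among them, while the other 27 keep at least 1 pair together. For lsm1-ideg T60 against T0, 1 of 35 splits called as many (real 1034, highest other 3). That share holds only if the numbers do not pair these libraries, which stays open, and with pairs the splits are again too few.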

How the results depend on the processing

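The settings named as features alone on their strand, leaving out both libraries that stand apart, leaving out the dcp2-ideg pair of number 4 and a robust dispersion estimate were chosen after seeing the data, as was the scaling of the features that changed in opposite directions, and so were scalings of gene list medians and of classes, and the others were planned. Where no reason is given, the cause was not tested. Fewer features were tested in the settings with protein-coding features alone, features alone on their strand and at least 10 CPM. Scaling and spread were also estimated anew there, and these influences on the counts were not separated. Of the 2325 protein-coding calls of dcp2-ideg beyond wt in the main fit, 1763 were still called when protein-coding features were fitted alone.

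The 4048 calls of dcp2-ideg beyond wt became 2218 among protein-coding features (1205 higher and 1013 lower), 6166 at T60 only and 2159 for features alone on their strand. Of the 4048, DESeq2 called 3986, limma-voom 3922 and total count scaling 2666, with 222 of the opposite sign there. The 25 calls of lsm1-ideg beyond wt became 101 with DESeq2, 55 with only the libraries of the compared groups, 39 among protein-coding features, 462 at T60 only, 47 without both libraries that stand apart, 101 without the dcp2-ideg pair of number 4, and 6 to 68 leaving out each replicate number. Of the 25, DESeq2 called 25 and limma-voom 17. The 3361 of dcp2-ideg against lsm1-ideg became 1774 among protein-coding features, 1712 for features alone, and 2141 to 3936 leaving out each replicate number. Within dcp2-ideg the 6102 became 3965 at 10 CPM, 3199 among protein-coding features and 3268 for features alone. Within lsm1-ideg the 218 became 431 with DESeq2, 1034 with the compared groups only, 504 without both libraries, 691 without the pair, 109 for features alone, and 30 to 433 leaving out each replicate number. The dcp2-ideg libraries enter no lsm1-ideg comparison with wt or within strain. Leaving them out can thus move those counts only through the spread, scaling and filter estimated over all libraries. The number of lsm1-ideg calls therefore depends in part on the joint fit. In wt DESeq2 called 1. At T0 the 97 of dcp2-ideg became 153 with DESeq2, 25 with the compared groups only, 59 among protein-coding features, 39 for features alone and 53 to 101 leaving out replicate numbers or libraries, and the 41 of lsm1-ideg became 81 with DESeq2, 73 without both libraries, 98 without the pair, 21 for features alone and 16 to 69.

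The 15 features called in both strains became 164 within strain, 6 and 7 with the wt libraries split, 26 under total count scaling, 64 with DESeq2, 26 at 10 CPM, 28 among protein-coding features, 31 without both libraries, 72 without the pair, and 6 to 47 leaving out each replicate number. With the replicate number as a block, lsm1-ideg beyond wt had 57 calls, 34 features were called in both strains in the same direction, and nitrogen catabolite repression passed in dcp2-ideg beyond wt. Only in dcp2-ideg did every pair of T0 and T60 libraries exceed 0.1 in the check on deviations, and 3 of those 4 libraries correlated best with their own number. The group means subtracted there included the outlying number 4, which can raise the correlations of the other numbers. In lsm1-ideg the correlations were 0.152, 0.120, 0.0665 and 0.143, and 4 of 4 libraries correlated best with their own number. That is a hint of pairing from the data, not the design, and pairing in lsm1-ideg stays open. The block moved the calls within lsm1-ideg from 218 to 290 and within dcp2-ideg from 6102 to 6347.

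With an estimated correlation, the gene lists that passed numbered 6 for dcp2-ideg beyond wt, 4 for lsm1-ideg beyond wt, 5 for their difference, 3 within each degron strain, 0 in wt, 1 for dcp2-ideg and 2 for lsm1-ideg at T0, where the lists that lost their call had estimates above the preset value. With fry they numbered 22 for dcp2-ideg beyond wt, 21 for the difference and 25 within dcp2-ideg, more than the 17, 17 and 18 with camera. With fry they were fewer than with camera elsewhere, at 4 for lsm1-ideg beyond wt, 9 within lsm1-ideg, 0 in wt and 1 and 2 at T0.

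Under total count scaling, list medians turned positive for decapping (0.092) and deadenylation (0.083) factors in dcp2-ideg beyond wt, and for deadenylation factors (0.088), iron starvation (0.025) and ergosterol (0.034) in dcp2-ideg against lsm1-ideg. Genes that turned were LSM1 (0.12 beyond wt and 0.22 within dcp2-ideg), SKI3 (0.083 against lsm1-ideg and 0.025 within dcp2-ideg), NOT3 (0.022), PGK1 (0.000292) and CDC5 (0.083) within dcp2-ideg. The protein-coding median turned to 0.32 in dcp2-ideg and 0.0086 in lsm1-ideg beyond wt. Of the 15 features that fell within dcp2-ideg and rose within lsm1-ideg, 3 were still lower in dcp2-ideg under total count scaling and 1 was called. All these reversals follow from the shift of every feature under that scaling. The protein-coding median in dcp2-ideg was -0.23 with median-of-ratios factors, -0.057 at 10 CPM and -0.079 for features alone. The XUT median was 1.43 under total count scaling, 1.49 at 10 CPM and 1.05 without both libraries. The SUT median was 1.44, 1.42 and 1.01 in those settings and 0.42 for features alone, and in lsm1-ideg 0.21 under total count scaling.

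Among genes and lists named singly, 344 results over all settings lost and 163 gained their call in the same direction. For the 14 named genes called in lsm1-ideg beyond wt, leaving out libraries or replicate numbers gave 280 results, each of 1 gene in 1 setting. Of these results 55 lost the call, as did 9 of 1600 for the 80 named genes called in dcp2-ideg beyond wt. In lsm1-ideg beyond wt HSP82, LIA1, TMC1, PRB1, STI1, CWP1, SSA4, GPP1, SAM2 and YNR068C each lost their call in at least 1 such setting. In simulated data at this depth, 1.5-fold changes were recovered in 7 of 100 and 6 of 100 features of these comparisons. Changes of 2-fold were recovered in 23 of 100 and 32 of 100, so changes of 2-fold or less could often be missed.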

Other observations

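The 17 features described first were singled out after their values were seen, and no test here was planned for them. These features were called in opposite directions within the degron strains from T0 to T60 under TMM scaling. Of the 17, 15 fell in dcp2-ideg and rose in lsm1-ideg, 13 are protein-coding and 6 are heat shock factor targets, namely SIS1, SSA2, HSC82, SSE1, YDJ1 and FES1. SSA2 has a near-identical copy and is uncertain. The 17 are not all separate, as CUP1-1 and CUP1-2 had nearly equal values (-0.46 in dcp2-ideg and 0.90 in lsm1-ideg for both). Reads may not tell these 2 genes apart, so both values are uncertain. By position the dubious open reading frame YDR154C overlaps CPR1. CUT894 ends where SSE1 starts, at 350122 on chromosome XVI. CUT509 (chromosome IV, 768107 to 768371) lies close to CPR1 (768412 to 769050), so these 2 CUTs may not be separate from their neighbours either. HSC82 changed by -0.50 ± 0.11 (SE) in dcp2-ideg and 0.71 ± 0.12 in lsm1-ideg, SIS1, which encodes an Hsp40 co-chaperone, by -0.80 ± 0.25 and 0.99 ± 0.25, LIA1 by -0.34 ± 0.11 and 1.03 ± 0.11, and the snoRNA snR44 by -1.36 ± 0.14 and 0.52 ± 0.14. Under total count scaling, which raised the 17 in dcp2-ideg by a median of 0.54, only 3 of the 15 were still lower there. They were snR44 at -0.81 ± 0.15 (adjusted p = 5.0e-05), SIS1 at -0.24 ± 0.25 (adjusted p = 0.405) and CUT894 at -0.018 (adjusted p = 0.926). HSC82 was then at 0.050, FES1 at 0.012, SSE1 at 0.066, YDJ1 at 0.17 and SSA2 (uncertain) at 0.20, none of them called in dcp2-ideg, so falls of these genes depend on the scaling. The citrate synthase gene CIT1 went the other way, with 0.27 ± 0.11 in dcp2-ideg and -0.54 ± 0.11 in lsm1-ideg.

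Among the 25 features called in lsm1-ideg beyond wt, 6 that rose were not protein-coding by the classes used, namely XUT_16F-36 (2.21), XUT_4R-365, CUT_GIM_1062, CUT_GIM_1100 and the dubious open reading frames YAL004W and YLR112W, all chosen after their values were seen. By position 4 of them lie inside a gene that also rose. CUT_GIM_1100 lies within AHA1 on the same strand, so its rise cannot be told from that of AHA1. XUT_4R-365 lies within AHA1, CUT_GIM_1062 within RNR2 and YAL004W within SSA1, each on the opposite strand, and reads of these genes assigned to the wrong strand were not excluded there. Over the 22 features chosen for rising in lsm1-ideg beyond wt, the median changes beyond wt were 1.36 in lsm1-ideg and 0.85 in dcp2-ideg. Smaller classes in dcp2-ideg beyond wt had medians of -0.38 for snoRNAs and snRNAs (9 of 84 fallen, 0 risen) and 0.048 for transposons (10 of 140 risen, 0 fallen). For tRNAs the median was -0.25 (4 of 88 risen, 2 fallen). For rRNA features 12 of 38 fell and 4 rose (median 0.19, Fisher adjusted p = 0.0179 for falls), and in the class of other features 14 of 34 rose and 1 fell (adjusted p = 0.00295 for rises). At T0, 11 of 38 rRNA features were already higher in dcp2-ideg than in wt (Fisher adjusted p = 1.5e-15) and 0 lower, in libraries selected for poly(A) RNA. Only 3 of the 40 rRNA features of the table overlapped no other feature on their strand, so most appear to share reads. Fisher's test takes features as independent, so its p-values for the rRNA features do not measure separate changes.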
